A study of Mus musculus with 12 samples.

How the data were processed

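The study sequenced total RNA from basal epithelial cells of the mouse hard palate. The cells came from 6 FVB mice that carried the transgenes K5-tTA and tetO-H2B-GFP, in which a keratin 5 promoter drives a transactivator and the transactivator drives a histone H2B joined to GFP. Doxycycline shuts the reporter off, so a cell keeps its green histone label until cell division dilutes it. After a chase of 14 days, dissociated cells positive for CD49f (integrin α6, a surface protein of basal keratinocytes) were sorted into a GFP-HI and a GFP-LO fraction, which the submitters describe as infrequently and frequently dividing cells. Per the labels' protocols, RNA came from small pools of sorted cells (200 to 1000), and libraries were made with the NuGEN SoLo kit for low-input total RNA.

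The deposited file is 1 table of read counts per gene, whole numbers that were not normalised, for 23420 genes in 12 libraries. The submitters' processing notes name bcl2fastq 2.20.0, FastQC, featureCounts, DESeq2 and R 3.4.1, and the builds mm10 and GRCm38. The file headers give each gene its exon intervals, strand and exonic length, so the counts are of reads over annotated exons. The aligner, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads from near-identical genes could therefore be split or lost, reads from overlapping genes could be assigned to either, and counts of clustered histone genes and ribosomal protein genes are uncertain for single members. Every count column matched 1 library by its name, and none was left unused.

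Totals ranged from 6678444 to 10547665 counts per library. The 45S pre-ribosomal RNA gene, Rn45s, held 31.5% to 59.8% of them, which left 4030757 to 6419834 counts for other genes. A gene with 0 counts could have had up to 3 counts by chance, a ceiling of 0.258 to 0.433 CPM (counts scaled to a common library total) in the different libraries. Such ceilings cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The table has no mitochondrially encoded gene, so the usual mitochondrial measure of cell damage could not be computed.

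Groups and mice were taken from the sample labels. The series text calls the samples matched, and the titles give both libraries of a pair the same animal code, so mouse was a block in every main fit. As a check, each library's deviation from its group mean was correlated with that of the other libraries across genes. The correlation within a mouse was 0.24 in B1M, 0.26 in B3M, 0.23 in B4M, 0.49 in B5M, 0.39 in B7F and 0.46 in B7M, and in each mouse it was higher than with any other mouse (at most 0.26). The mice were 49 days old except B7F, at 71 days. By its sex-linked transcripts B7F was also the only female, so age and sex could neither be tested nor told apart. The labels name no sequencing or library batch, so values within batches could not be given beyond the fits that leave out single mice.

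Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by group (minimum count 10, minimum total 15), which left 11719, and libraries were scaled by trimmed mean of M-values (TMM). The quasi-likelihood test was fitted with robust estimation, was two-sided and used an adjusted p (Benjamini-Hochberg) under 0.05. CPM in the text are normalised by these factors, and log2 fold changes are GFP-HI over GFP-LO with their standard error (SE). Gene lists for 32 pathways, cell states and cell types were fixed before the data were examined. Of their 669 symbols, 650 were in the table, some under older names matched through RefSeq synonyms. The 23 lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a correlation between genes preset at 0.01. As alternatives the correlation was estimated per list and fry was run.

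A rule for the genes named in the text was also fixed before the data were examined. It takes up to 12 called genes in each direction with the largest fold change, a mean of at least 5 CPM and the same direction in all 6 mice. It adds up to 4 members of each tested list with the smallest p, and a fixed set of markers (Itga6, Krt5, Krt14, Trp63, Krt10, Krt13, Mki67, Top2a, Ccnb1, Cdkn1a, Cdkn1b, Lrig1, Lgr5, Lgr6, Sox2 and Pitx1). Icam1, Ctsl, Kif15, Smtn, Zfp704, Snord17, Slc1a3 and Cd247 lie outside the rule and are named because they passed a test, a choice made after their values were seen. The histone variants H2afz, H2afv, H2afy, H1f0, H3f3a and H3f3b were added in the same way, for comparison with the clustered genes. Treating the clustered histone genes as a family was also decided after the values were seen. Values of single measures per mouse were compared by exact two-sided sign-flip permutation, whose smallest p with 6 pairs is 0.03125.

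The gene test was run on simulated counts with the means and library sizes of the real libraries and 200 genes changed among 11719. It recovered 28 of 100 genes changed 1.5-fold and 51 of 100 changed 2-fold, and 6 of its 85 calls were unchanged genes (7.06%). A simulated list of 25 genes shifted 1.3-fold was called, and 0 of 30 unchanged lists were. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called in error. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom with quality weights, no robust estimation, no mouse block, thinned counts, other thresholds, and each mouse left out in turn. Fits without B1M and B3M together, without Rn45s, with histone genes summed by class and with shared genes left out of lists were added after seeing the data.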

Results

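The data are expression profiles of palatal basal epithelial cells from 6 mice, each giving a library of GFP-HI cells and a library of GFP-LO cells. The fractions were sorted by their level of the H2B-GFP label after the 14-day chase. The libraries hold no measure of the label at the start of the chase, so how often the cells had divided is not shown by these data. Both fractions were sorted as CD49f-positive, so the comparison asks which genes differ between basal cells that the submitters label as infrequently and as frequently dividing. Totals without Rn45s were 4244141 to 5865807 counts in the GFP-HI libraries and 4030757 to 6419834 in the GFP-LO libraries, and 15600.5 ± 2592 and 15531.5 ± 1473 genes were detected (SD, n = 6 each). Rn45s took 40.3% ± 10.3 of counts in GFP-HI and 42.8% ± 7.11 in GFP-LO (SD, n = 6; exact sign-flip p = 0.3125). The GFP-HI libraries of B1M and B3M detected the fewest genes, 12312 and 12810.

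Both fractions expressed genes of basal keratinocytes at high levels. Krt14 and Krt5, the keratins of the basal layer, stood at 10198 ± 2894 and 5194 ± 698 CPM in GFP-HI and at 10977 ± 1873 and 5827 ± 915 CPM in GFP-LO (SD, n = 6). Trp63, a transcription factor of stratified epithelia, had 625 ± 72.8 and 647 ± 66.7 CPM, and Itga6, which encodes the antigen used for sorting, 563 ± 86.9 and 611 ± 82.5 CPM. In edgeR's quasi-likelihood test none of these 4 genes passed (log2 fold changes −0.14, −0.16, −0.05 and −0.12; adjusted p = 0.76, 0.42, 0.88 and 0.77). The whole basal keratinocyte list of 18 tested genes had no call, also when adjusted over the list alone, and a median log2 fold change of −0.05 (camera adjusted p = 0.64).

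Most genes that differed between the fractions were replication-dependent histone genes, which supply the proteins that package newly made DNA. Of 57 tested genes of the histone clusters, 42 were higher in GFP-HI, 0 were lower, and 56 had a positive log2 fold change, with a median of 0.63. Summed over the family, histone transcripts made up 9853 ± 4718 CPM in GFP-HI and 6290 ± 2830 CPM in GFP-LO (SD, n = 6). The mean log2 difference within mice was 0.63 ± 0.127 (SD, n = 6), or 1.55-fold, and it was positive in 6 of 6 mice (exact sign-flip p = 0.03125, the smallest possible). All 5 histone classes were higher when each class was summed and tested as 1 gene with edgeR, by log2 0.44 for linker histone H1, 0.65 for H2A, 0.62 for H2B, 0.69 for H3 and 0.63 for H4 (adjusted p = 0.020, 0.0014, 6.8e-04, 6.8e-04 and 6.8e-04). The family was grouped after the values of its members were seen in these libraries, so the tests of sums are no independent evidence.

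Most of these genes, 47 of the 57, lie on chromosome 13 between 21715763 and 23934156 (mm10), and 8 lie on chromosome 3 between 96219916 and 96270192. Chromosomes 11 and 6 hold 1 each. Members named by the rule included Hist1h3a, an H3 gene of 1 annotated exon (chromosome 13, 23761853 to 23762386), at 255 ± 157 CPM in GFP-HI against 137 ± 64.0 CPM in GFP-LO (SD, n = 6; log2 fold change 0.81 ± 0.09 SE, adjusted p = 0.0012). Hist1h2bb, an H2B gene at 23746734 to 23747201 on the same chromosome, was at 337 ± 177 and 191 ± 84.9 CPM (log2 fold change 0.78 ± 0.08 SE, edgeR adjusted p = 6.8e-04). Hist1h3b, Hist1h3c, Hist1h4b, Hist1h2af and Hist1h2ae were higher by log2 0.75, 0.73, 0.73, 0.73 and 0.73. These copies are close in sequence, so the values of single members are uncertain while the class sums do not depend on how reads were shared within a class. Of the other 11662 tested genes 13 were higher, or 0.111% against 73.7% of the histone genes, a family grouped after the values were seen. The 7 histone variant genes looked up did not pass and went in both directions. Their log2 fold changes were 0.51 for H2afv, 0.43 for H2afx, 0.38 for H2afz, 0.01 for H3f3b, −0.01 for H3f3a, −0.11 for H1f0 and −0.31 for H2afy (adjusted p = 0.27, 0.11, 0.28, 0.98, 0.99, 0.80 and 0.50).

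**Figure D1:**
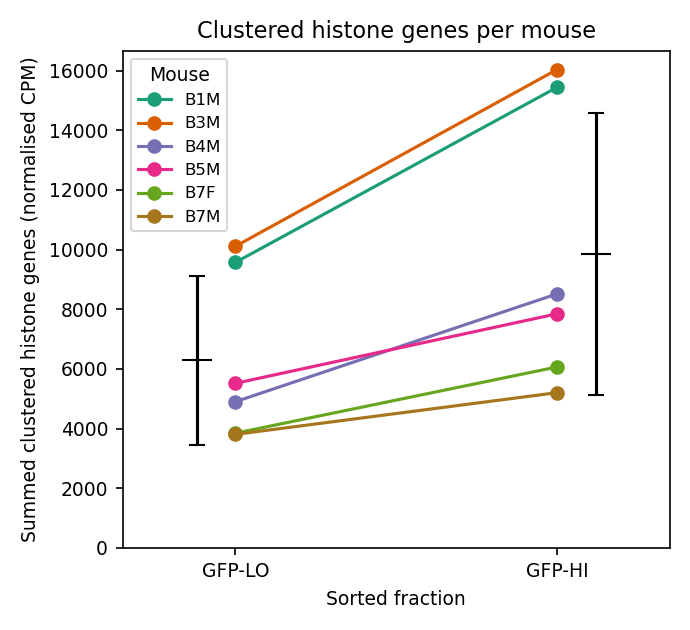
Summed clustered histone genes (normalised CPM, vertical axis) in the GFP-LO and GFP-HI library of each mouse, joined by a line per mouse, with mean and SD (n = 6) as black bars beside the points. All 6 lines rise from GFP-LO to GFP-HI, and both libraries of B1M and of B3M lie above those of the other 4 mice.

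Histone levels also differed between mice. The sums were 15444 and 16040 CPM in the GFP-HI libraries of B1M and B3M, the same libraries that detected the fewest genes, and 5204 to 8517 CPM in the GFP-HI libraries of the other 4 mice. In GFP-LO they were 9570 and 10110 CPM in B1M and B3M and 3804 to 5516 CPM in the others. Some short genes outside the family were also highest in the GFP-HI libraries of B1M and B3M. Rps20 was at 1076 and 1077 CPM there and at 415 to 648 CPM in the others. Snord17 was at 1060 and 1234 CPM against 400 to 564 CPM. Ndufa5, of 549 bases, did not share this, at 19.8 and 20.6 CPM against 21.5 CPM in B4M. Whether this mouse difference belongs to histone genes or to short genes in general was not tested. The number of histone genes called higher, 42 with all mice, was 22 without B3M and 24 without B4M, where the family's median log2 fold change was 0.61 and 0.59. With B1M and B3M both left out, a fit added after seeing the data, it was 49 and the median was 0.61.

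The list of genes for G2/M and mitosis was shifted up with the preset correlation (camera adjusted p = 4.2e-12) but not with an estimated correlation (adjusted p = 0.26). Top2a, the topoisomerase that untangles replicated chromosomes, was higher in GFP-HI (512 ± 76.2 against 371 ± 76.6 CPM, SD, n = 6; log2 fold change 0.48 ± 0.08 SE, edgeR adjusted p = 0.019), although the difference in B5M was only 0.01. Kif15, a mitotic kinesin, was higher as well (69.1 ± 16.6 against 44.9 ± 6.28 CPM; log2 0.60 ± 0.11 SE, adjusted p = 0.025). Of the 25 genes of the list, 23 had a positive log2 fold change, with a median of 0.34. Top2a was the 1 member called over all genes, and 17 members passed when adjusted over the list alone. Among the members that did not pass over all genes, the proliferation marker Mki67 had log2 0.37 (adjusted p = 0.097), the spindle genes Tpx2 and Nusap1 0.57 and 0.50 (adjusted p = 0.071 and 0.097), and Ccnb1, the cyclin of mitotic entry, 0.29 (adjusted p = 0.74).

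For DNA replication and S phase, 23 of 25 tested genes had positive values and the median was 0.35. None passed over all genes, and 2 passed when adjusted over the list alone, Rrm1, which encodes the large subunit of ribonucleotide reductase, and Mcm6, part of the replicative helicase (log2 0.36 and 0.59; adjusted p over all genes = 0.073 and 0.24). Rrm2 and Dut, which also serve the supply of nucleotides, had log2 0.47 and 0.46 and did not pass (adjusted p = 0.57 and 0.60). The list was shifted up (camera adjusted p = 4.1e-09), and this was the 1 list called with an estimated correlation (adjusted p = 0.021) and by fry's directional test (adjusted p = 0.0012). Its mean was positive in 6 of 6 mice, at 0.32 ± 0.079 (SD, n = 6).

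DNA repair genes had a median log2 fold change of 0.39 over 21 tested genes, with 14 positive and 7 negative. None passed over all genes and 1, H2afx, whose histone marks DNA breaks, passed when adjusted over the list alone (log2 0.43, adjusted p over all genes = 0.11). Fanca and Fancd2, of the pathway that repairs DNA crosslinks, had log2 1.02 and 0.67 (adjusted p = 0.33 and 0.43). The shift of the list had camera adjusted p = 0.0013, and adjusted p = 0.37 with an estimated correlation. Its mean was positive in 4 of 6 mice.

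No shift was detected for genes of cell cycle exit and quiescence. In this list 0 of 20 tested genes passed, over all genes or over the list alone, and the median was 0.11 (camera adjusted p = 0.22). The cyclin-dependent kinase inhibitors Cdkn1a and Cdkn1b had log2 fold changes of 0.04 ± 0.09 and −0.06 ± 0.10 (SE, n = 6; edgeR adjusted p = 0.94 and 0.93). Cdkn2c, another inhibitor of this kind, had 0.69 (adjusted p = 0.71), and Txnip, a redox regulator, 0.21 (adjusted p = 0.44).

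**Figure D2:**
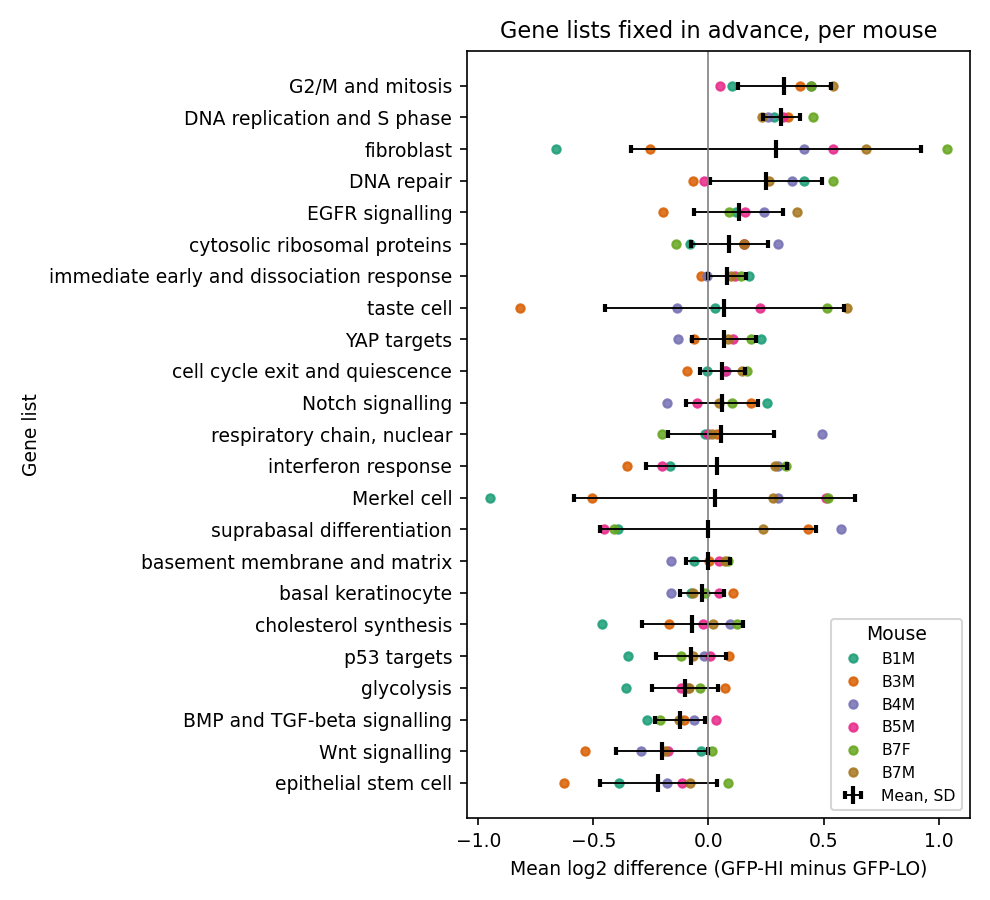
Mean log2 difference between GFP-HI and GFP-LO (horizontal axis) over the tested genes of each of the 23 lists, with 1 point per mouse and the mean and SD over 6 mice in black. The mitosis and DNA replication lists are the 2 lists whose points lie above 0 in all 6 mice, with means of 0.33 and 0.32. Exact sign-flip p was 0.03125 for each, the smallest that 6 pairs allow, and 0.36 after Benjamini-Hochberg adjustment over the 23 lists. With only 2 lists at the smallest p, the adjusted p could not fall under 0.05, so the adjustment does not decide for or against them.

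Outside the histone clusters, 13 genes were higher in GFP-HI. Nbea, a large scaffold protein of vesicle traffic (chromosome 3, 55625198 to 56183701), had the largest fold change, at 31.3 ± 21.7 CPM in GFP-HI and 9.86 ± 9.0 CPM in GFP-LO (SD, n = 6; log2 1.78 ± 0.22 SE, 3.43-fold, edgeR adjusted p = 0.0020). B2m, the light chain of MHC class I (chromosome 2, 122147687 to 122153082), was at 82.9 ± 19.0 and 45.9 ± 9.93 CPM (log2 0.85 ± 0.10 SE, 1.80-fold, adjusted p = 0.0012). Cyp2f2, a cytochrome P450, was higher by log2 0.83 ± 0.13 SE and Ctgf, a matricellular protein and target of YAP, by 0.75 ± 0.12 SE (adjusted p = 0.0067 and 0.0070). Cxcl1, a neutrophil-attracting chemokine, was higher by log2 0.73 ± 0.12 SE and Postn, the matrix protein periostin, by 0.67 ± 0.11 SE (adjusted p = 0.014 and 0.011). The remaining 7 were Smtn (0.71), Kif15 (0.60), the cathepsin gene Ctsl (0.58), the adhesion receptor Icam1 (0.57), Zfp704 (0.53), Top2a (0.48) and the small nucleolar RNA Snord17 (0.44).

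The 7 genes lower in GFP-HI included growth factor binding proteins and a Wnt ligand. Igfbp5 and Igfbp2, secreted proteins that bind insulin-like growth factors and lie near each other on chromosome 1 (72858065 to 72874865 and 72824480 to 72852471), fell by 1.06 and 0.73 on the log2 scale. Igfbp5 was at 22.0 ± 11.4 CPM in GFP-HI and 42.6 ± 11.3 CPM in GFP-LO, and Igfbp2 at 390 ± 181 and 606 ± 133 CPM (SD, n = 6; edgeR adjusted p = 0.020 and 0.0072). Wnt5a, a ligand of mainly non-canonical Wnt signalling (chromosome 14, 28505473 to 28525515), was at 14.7 ± 3.79 and 30.1 ± 7.96 CPM (log2 −1.02 ± 0.16 SE, adjusted p = 0.0067). Dcn, which encodes the proteoglycan decorin, was at 327 ± 83.9 and 456 ± 92.2 CPM (log2 −0.49 ± 0.07 SE, adjusted p = 0.0031). Fam213a, the plasma membrane calcium pump gene Atp2b4 and the calmodulin-like gene Calml3 had log2 fold changes of −0.56, −0.55 and −0.47 (adjusted p = 0.046, 0.021 and 0.027).

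**Figure D3:**
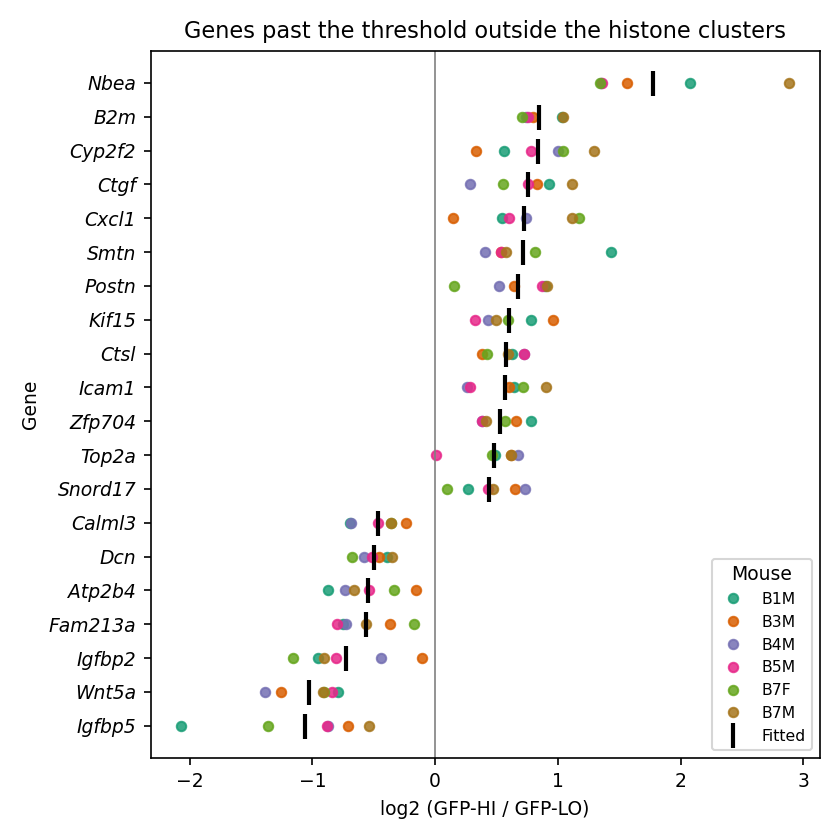
Log2 ratio of GFP-HI to GFP-LO (horizontal axis) for the 20 called genes outside the histone clusters, with 1 point per mouse and the fitted value as a black bar. All 6 mice lie on the same side of 0 for every gene shown, with Top2a in B5M closest to it at 0.01.

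Altogether edgeR called 55 genes higher and 7 lower among 11719, each in the same direction in 6 of 6 mice, and 848 genes had an unadjusted p under 0.05 against 586 expected by chance. Mouse was a block in this fit: without it, edgeR called 0 genes higher and 0 lower, with 293 and 147 at an unadjusted p under 0.05. Leaving out single mice moved the higher count to 29 without B3M and 30 without B4M, and the lower count to 14 without B1M, 4 without B3M, 2 without B4M, 3 without B5M and 4 without B7M. Of the 20 called genes outside the histone clusters, B2m, Ctgf, Ctsl, Dcn, Igfbp2 and Nbea were called with each mouse left out in turn, whereas Wnt5a was not called without B4M and Top2a was not called without B3M, B4M, B7F or B7M. With the histone genes summed into 5 classes, an alternative added after seeing the data, 12 genes or classes were higher and 3 genes lower. None of Top2a, Kif15, Icam1, Smtn, Zfp704 and Snord17 was called in that fit, nor were Igfbp5, Fam213a, Atp2b4 and Calml3.

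Markers of epithelial stem cells went in both directions. In this list of 18 tested genes, Igfbp5 was called over all genes, as lower, while 4 were higher and 2 lower when adjusted over the list alone. The higher ones were Lrig1, a membrane brake on EGF receptor signalling (24.7 ± 4.15 against 16.4 ± 3.27 CPM, log2 0.60), the secreted protein Dkk3 (0.49), the keratin Krt15 (0.32) and the glutamate transporter Slc1a3 (0.47). The lower ones were Igfbp5 and Lgr6, a receptor for R-spondins. Lgr6 had 12.1 ± 4.24 CPM in GFP-HI and 27.8 ± 5.38 CPM in GFP-LO (SD, n = 6), lower in 6 of 6 mice, and missed the threshold over all genes (log2 −1.25 ± 0.27 SE, edgeR adjusted p = 0.071). Its adjusted p over the other settings ranged from 1.5e-06 without a count filter to 0.57 without the mouse block. Lgr5 had at most 16 counts in a library and was not tested. Sox2 and Pitx1, transcription factors of oral epithelium, had log2 fold changes of −0.07 ± 0.13 and −0.01 ± 0.13 (SE, n = 6; adjusted p = 0.93 and 0.99). The list had no called shift (camera adjusted p = 0.72). Fry's test for changes in either direction passed for 10 of the 23 lists, with adjusted p = 0.0019 for this one. It also passed for YAP targets (9.6e-07), Wnt signalling (2.1e-06), DNA replication and fibroblast genes (2.2e-04 each), immediate early genes (0.0029), mitosis (0.0042), matrix (0.0057), EGF receptor signalling (0.025) and DNA repair (0.030).

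The Wnt signalling list was shifted down in GFP-HI with the preset correlation (camera adjusted p = 0.014) but not with an estimated correlation (adjusted p = 0.37). Of 20 tested genes 16 had a negative value, Wnt5a was the 1 call over all genes, and the median was −0.18. Adjusted over the list alone, Wnt5a and Lgr6 were lower while Sfrp1 and Dkk3, a secreted inhibitor of Wnt ligands and a relative of such inhibitors, were higher (log2 0.54 and 0.49; adjusted p over all genes = 0.29 and 0.40). The shift was not called without B3M, B4M or B7M (adjusted p = 0.11, 0.10 and 0.074), and the list's mean was positive in 1 of 6 mice, B7F.

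EGF receptor signalling genes had a median log2 fold change of 0.19 over 16 tested genes, of which 12 were positive. None passed over all genes, and 3 passed when adjusted over the list alone, all feedback regulators or ligands of the receptor, namely Lrig1, Spry1 (log2 0.44) and Hbegf (log2 0.35; adjusted p over all genes = 0.25 for Spry1 and 0.27 for Hbegf). The list was shifted up with camera adjusted p = 0.0048, against adjusted p = 0.20 with an estimated correlation, and its mean was positive in 5 of 6 mice.

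The list of cytosolic ribosomal protein genes had a small upward shift with the preset correlation (camera adjusted p = 1.0e-04) but not with an estimated correlation (adjusted p = 0.80). The median of 77 tested genes was 0.09, with 62 positive values and no call over all genes or the list alone. The 183 tested genes of at most 468 bases outside the histone clusters, some of them in this list, had a median of 0.13. Whether the shift belongs to the list or to short genes in general was not tested. Rps20 and Rps26 had log2 0.28 and 0.29 (adjusted p = 0.12 and 0.28). Without B4M the preset test gave adjusted p = 0.081. The list's mean was positive in 4 of 6 mice and negative in B1M and B7F (mean 0.09 ± 0.167 SD, n = 6; exact sign-flip p = 0.22).

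The remaining signalling and matrix lists had no called shift, and their calls were single genes. YAP targets had 1 call among 13 tested genes, Ctgf, whereas the target Cyr61 had log2 −0.18 (adjusted p = 0.76; camera adjusted p = 0.47 for the list). Basement membrane and matrix genes had 1 call among 15, Postn. Adjusted over the list alone, Lamb2, a laminin chain, was also higher and Fras1, a basement membrane protein, lower (log2 0.49 and −0.77; camera adjusted p = 0.84 for the list). No gene passed, over all genes or the list alone, among 13 tested of Notch signalling, 23 of BMP and TGF-beta signalling and 17 p53 targets (camera adjusted p = 1.00, 0.62 and 0.77). Jag1, a Notch ligand, had log2 −0.19, and Bambi, a decoy receptor for BMP and TGF-beta, −0.58 (adjusted p = 0.66 and 0.50).

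Differentiation, stress and metabolic lists had no called shift. Suprabasal differentiation had 1 call among 21 tested genes, Calml3, also over the list alone, and a median of 0.04 (camera adjusted p = 0.99). Krt10 and Krt13, keratins of suprabasal cells, varied widely, at 142 ± 136 and 670 ± 436 CPM in GFP-HI against 65.7 ± 54.7 and 458 ± 259 CPM in GFP-LO (SD, n = 6; log2 0.71 and 0.42, edgeR adjusted p = 0.86 and 0.65). Both were called as higher in 2 of 19 other settings, without a count filter and with limma-voom and quality weights. Immediate early genes, which cell dissociation can induce, had 1 call among 24, Cxcl1, while Fosb had log2 0.36 (adjusted p = 0.43; camera adjusted p = 0.11 for the list). Among 9 tested interferon response genes, 15 of glycolysis, 20 of cholesterol synthesis and 67 of the nuclear-encoded respiratory chain, none passed over all genes or the list alone. Their camera adjusted p were 0.64, 0.62, 0.91 and 0.094, and without B7F the respiratory chain list was called as shifted up (adjusted p = 0.0021). The mean of that list was 0.49 in B4M, −0.20 in B7F and −0.01 to 0.04 in the other mice. With all mice and an estimated correlation, its camera adjusted p was 0.88.

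Transcripts of other cell types were mostly scarce in both fractions. The fibroblast list had 1 call among 9 tested genes, Dcn. Adjusted over the list alone, Fbn1 was higher (log2 0.91), and the list had no called shift (camera adjusted p = 0.62). Its mean log2 difference was −0.66 in B1M and −0.26 in B3M and 0.42 to 1.04 in the other 4 mice, and without B1M and B3M together the list was called as shifted up (adjusted p = 0.0066). Col1a1, a major fibroblast collagen, was at 2.88 ± 1.84 CPM in GFP-HI and 0.878 ± 0.714 CPM in GFP-LO (SD, n = 6; log2 1.55 ± 0.73 SE, adjusted p = 0.69). Merkel cell and taste cell lists had 6 tested genes each, no call over all genes or the list alone, and camera adjusted p = 0.99 and 0.77. Too few genes were detected to test the lists for melanocytes (4 tested), Langerhans cells and macrophages (4), Schwann and neural cells (4), salivary gland (3), T and NK cells (2), skeletal muscle (2), endothelium (1) and erythroid cells (0). None of their genes passed over all genes, and 1, the T and NK cell gene Cd247, passed over its list alone (log2 0.81). Without a count filter, which lets these lists be tested, the salivary gland list was called as shifted up (camera adjusted p = 0.031). No gene of the mitochondrially encoded list was in the table.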

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

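In 88 sets of 6 values, a library or mouse far from the others was sought, and 5 were found, against 4.4 expected by chance at about 1 in 20. The GFP-LO library of B3M had 6419834 counts without Rn45s, against 4030757 to 4859455 in the other 5 GFP-LO libraries. For Top2a, the log2 difference between GFP-HI and GFP-LO was 0.010 in B5M and 0.46 to 0.67 in the other 5 mice. For Fras1, this difference was −1.90 in B1M and −0.75 to −0.11 in the other 5 mice. Cd247, a gene of low counts, differed by 2.39 in B3M and by 0.25 to 1.01 in the others, and H2afz by −0.14 in B7F and by 0.34 to 0.61 in the others. Their number is close to what chance gives, and no explanation was tested for them.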

How the results depend on the processing

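The called genes named in the text kept their direction in every setting run, and the fits differed mainly in how many genes they called. Counts of genes higher and lower, 55 and 7 in the reported fit, were 127 and 45 without a count filter, 112 and 25 with DESeq2, and 211 and 69 with limma-voom and quality weights, which gave B1M and B3M the lowest weights. Without B1M and B3M together they were 117 and 34. In each of these 4 settings the calls included all 55 and all 7. No gene in either direction was called without the mouse block or when tested against a change of 1.5-fold (0 and 0). With histone genes summed by class the counts were 12 and 3, and 14 genes were lower at an adjusted p under 0.1. Leaving out 1 mouse gave 29 to 81 higher and 2 to 14 lower genes. Other scalings, a stricter filter, leaving out Rn45s or the 10 most abundant genes, thinned counts and no robust estimation kept each count within 1.5 times.

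Of the 6 shifted lists, 1 was called with an estimated correlation and 1 by fry's directional test. Other settings gave 4 to 7, and removing the mouse block ended no list call. List tests were not run with DESeq2, and quality weights and robust estimation do not enter them. Signs turned only for genes near 0. Pitx1, at −0.01 as reported, was 0.0028 with DESeq2's size factors, 9.9e-04 with DESeq2, 0.017 with thinned counts and 0.078 without the mouse block, with a range of −0.13 to 0.086 over fits leaving out 1 mouse. H3f3a (−0.01) was 3.6e-04 without the mouse block and 0.010 without B1M and B3M, and H3f3b (0.01) was −0.014 with upper-quartile scaling and −0.0013 without a count filter. Over fits leaving out 1 mouse, H3f3a ranged from −0.046 to 0.030, H3f3b from −0.025 to 0.081, Cdkn1a from −0.0082 to 0.11 and Sox2 from −0.14 to 0.0074. The fit without the block adds the spread between mice to the error. The test against 1.5-fold asks for a larger change. Summing the histone genes puts 5 rows in place of 57, of which 42 were called. With fewer small p-values, the Benjamini-Hochberg adjusted p of genes ranked below them rises. For the other changes in counts the cause was not tested. The simulation recovered 28% of genes changed 1.5-fold, so a gene changed by that much was more often missed than found at this depth and number of mice.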

Other observations

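Of 7 genes of MHC class I antigen presentation looked up after B2m was called, a choice made after values were seen, 6 had a higher mean in GFP-HI. None of the 5 that could be tested was called, and Psmb8 and Psmb9 had too few counts to be tested. H2-K1 was at 86.4 ± 21.4 CPM in GFP-HI and 67.5 ± 13.8 CPM in GFP-LO (SD, n = 6), higher in 6 of 6 mice. H2-D1, Tap1, Tapbp, Tap2 and Psmb9 were higher in 5, 5, 4, 3 and 4 mice, and Psmb8 was higher in 1. No test of these genes as a group was made. Transcripts of 4 MHC class II genes (Cd74, H2-Aa, H2-Ab1 and H2-Eb1) differed between mice far more than between fractions. Their sum was 21.4 to 33.2 CPM in the 4 libraries of B5M and B7F and 0.126 to 2.75 CPM in the other 8 libraries. In the lists of other cell types, the most abundant gene of each list had very different levels. Besides Dcn of the fibroblast list, at 327 ± 83.9 CPM in GFP-HI and 456 ± 92.2 CPM in GFP-LO, these were Slc12a2 of the salivary gland list (250 ± 53.4 and 239 ± 45.7 CPM) and the taste cell gene Itpr3 (218 ± 31.6 and 235 ± 41.0 CPM). L1cam of the Schwann and neural list was at 54.3 ± 15.02 and 48.7 ± 6.67 CPM, Sox2 of the Merkel cell list at 43.7 ± 9.42 and 45.8 ± 9.33 CPM, and Thy1 of the T and NK cell list at 37.4 ± 10.5 and 33.3 ± 3.62 CPM. Mfge8 of the Langerhans cell and macrophage list was at 18.8 ± 6.93 and 16.8 ± 4.36 CPM, and the top genes of the melanocyte, skeletal muscle, endothelial and erythroid lists had means of at most 7.54 CPM in either fraction. Both fractions also held many counts of the non-coding RNA Rmrp, at 9872 ± 3788 CPM in GFP-HI and 8013 ± 2293 CPM in GFP-LO. Xist had 24875 and 25218 counts in the libraries of B7F and 11 to 45 in the other 10, while Ddx3y had 1 to 2 counts in B7F and 422 to 1166 in the others, so both libraries of every mouse matched in sex.

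Of the tests that follow, those on chance and on short genes were chosen before their results were seen, and those on transgene reads, exchanged labels, cells in S phase, fibroblasts and immune cells after. The counts of genes argue against chance. With 6 pairs only 32 splits within mice exist, so chance cannot be excluded beyond 1 in 32. Of the 32 ways to swap the 2 libraries within mice, 1, the real one, gave 55 genes in one direction and 1 gave 7 in the other, and the highest count in any other was 0. The higher and lower counts are not separate evidence. Of the 55 genes, 42 are clustered histone genes, and with those summed by class 3 genes were lower. Of 100 splits of the 12 libraries drawn without regard to mice, 1, the real one, gave 62 or more calls, and the highest other was 30, in a split that parted the libraries of 2 mice. The real split parts all 6 pairs, as do the 32 swaps, whereas most random splits part fewer.

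Higher histone transcripts in the fraction labelled as infrequently dividing are the pattern a biologist may most want to follow up. Reads of the H2B-GFP transgene counted on H2B genes would raise that class alone, but the genes of the other 4 classes had a median log2 fold change of 0.65. A general shift of short transcripts falls short of the full difference. The 183 other tested genes of at most 468 bases had a median of 0.13 (95% bootstrap interval 0.074 to 0.166). This lay below a bound of 0.31, a fixed fraction of the observed histone median. The fraction was chosen before the result of this test was seen, but the bound itself comes from these data. That interval resamples genes and does not measure the spread between mice. The median of these short genes was above that of all tested genes (−0.02) and below that of the histone genes (0.63). A length effect could therefore account for a part of the histone difference. A hypothesis that remains open is that GFP-HI held more cells between S phase and mitosis at the time of sorting; the DNA replication list had a mean log2 difference of 0.32 and was positive in 6 of 6 mice, but these values were known when the hypothesis was made and are no independent test of it, and DNA content was not analysed here. Labels exchanged in all mice cannot be told apart from this, because the table has 0 rows for the transgene, whereas an exchange in some mice only would not give the same direction in all 6.

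Decorin is known best from fibroblasts, which lie under the epithelium and which the CD49f gate is meant to leave out, and carried-over fibroblasts in GFP-LO are a candidate explanation for the Dcn difference. The 3 collagens Col1a1, Col1a2 and Col3a1 together reached at most 0.785% of the Dcn level in any GFP-LO library. So low a share argues against such cells as the source, although no fibroblast profile was used to set the share they would bring. No biological explanation was tested.

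More antigen-presenting immune cells in GFP-HI might account for the B2m difference. The 4 MHC class II genes together were higher in GFP-HI in 1 of 6 mice, B1M, at 0.491 against 0.126 CPM, or 4 against 1 counts. In B1M, B3M, B4M and B7M they had at most 19 counts in a library, too few to read a direction. In B5M and B7F, where they were most abundant, they were at 21.4 and 21.9 CPM in GFP-HI against 33.2 and 25.4 CPM in GFP-LO. For B5M and B7F, that argues against such cells as the source. Whether interferon or another signal raised B2m in GFP-HI cells stays open, and the interferon response list had no called shift.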
